A study of Mus musculus with 10 samples.

How the data were processed

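The series holds 10 samples from 3 mice: 7 tumors and 3 samples of adjacent normal colon epithelium. Per the labels, total RNA was turned into biotin-labelled cRNA by T7 amplification and stained with Alexa-647. The spot intensities were read, per the file headers, on a GenePix 4000B scanner at 635 nm, with 5 micrometre pixels and a photomultiplier gain of 650, and quantified with GenePix Pro 4.1.1.4. The oligonucleotide set is MEEBO, a mouse exon-based collection, per the file headers, with 38880 spots per array. The scanner values are linear and not normalized. The authors' deposited table holds linear intensity values of 19327 probes: each is the spot median minus local background times 1 factor per array (within 0.1% for at least 99.95% of the probes), with column medians from 110.2 to 118.9. How its probes were chosen is not given in the sources used here.

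Gene probes (34312, by ID prefix) carry accessions. Of these, 22987 matched 1 gene symbol through RefSeq accessions without versions in a table of the GRCm38.p6 assembly, 5232 kept the file's accession and 6093 had none and were left out of the main tests. The build behind the array is not given in the sources used here, so that table was used only for names and for which genes neighbour each other. Background was corrected with normexp (offset 50) on the spot mean and local background median of all spots, and gene probes were quantile normalized; 43 probes marked bad on an array were left out. The spot mean is the default of limma for this scanner. The design fixed beforehand did not say mean or median, and the mean, the limit for above background and the handling of unnamed probes were settled after the intensities were seen and before any test was run. A probe was above background where it was found by the scanner software and exceeded the 99th percentile of the 432 null spots on that array. Genes above background on at least 3 arrays were kept, with the probe of highest mean for each, giving 14478 genes, 11741 of them with a symbol. A gene not above background on any array of a group has only a bound, computed as the brighter group's mean over the dim group's mean of, per array, the higher of the lowest signal above background and the probe's own.

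Tumors and normals were compared with limma (lmFit and eBayes) with the mouse as a fixed block, since the labels give the animal of every sample. A Benjamini-Hochberg adjusted p under 0.05 was required. Deviations of the normals and of the mean tumors of the same mouse from their group means had correlations of 0.11, -0.067 and -0.078, so the pairing comes from the animals, not from these values. The 7 tumors share 3 animals and are not independent animals. Tumors of mouse 42 and mouse 41, and their tumor minus normal differences, were compared with means per mouse and tissue. The 25 gene lists were fixed before the data were examined and tested with camera (preset correlation 0.01, and an estimated one) and fry. Fry asks whether the genes of a list move one way on balance and does not compare the list with other genes. The fits were tested on simulated data: of genes changed by 0.5 and 1 on the log2 scale, 44% and 94% were recovered in the tumor minus normal fit of 14478 genes, 16% and 86% between the tumors of mouse 42 and 41, and 0% and 4% for the difference of effects, with 6.63%, 3.82% and 8.91% false among the calls. The simulated noise was independent between genes and arrays, with 50 genes changed at each size and no scan session or correlation between genes. For the comparisons of the mice it held no other mouse effects and gave the single normals the same spread as the other arrays. The rates of false calls therefore need not hold for these data.

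Genes are named by a rule fixed beforehand. It takes the 12 with the largest difference in each direction among genes past the threshold, on the same side of the own normal in all 7 tumors and above background on all arrays of the higher group. It adds up to 4 members of each list with the lowest p, Ctnnb1, Cyp1a1, Cyp1a2 and the sex-linked genes, and the 5 largest differences past the threshold in each direction in each comparison of mouse 42 and mouse 41. Some genes that this rule takes are not reported here. Alternatives covered background correction, normalization, filter, probe choice, model, block, threshold and left-out arrays or mice. The spot median, the scan session as a block and leaving out the 2 arrays with high squamous genes, with and without the block, were chosen after seeing the data. The 4 tumor arrays marked as redipped or rescanned were scanned at a later time of day than the other 6 arrays, per the file headers. They are called the later scan session here. The session and the repeated dip or scan fall on the same arrays, so these 2 cannot be told apart. R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.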

Results

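Gene expression was measured on 10 one-colour oligonucleotide arrays from 3 CYP1A-humanized mice, which carry human CYP1A genes in place of the mouse ones. The animals had received 2 doses of 100 mg/kg PhIP, a heterocyclic amine formed in cooked meat, and then 1.5% dextran sulfate sodium (DSS), which injures the colon epithelium. They were sampled at 16 weeks of age. The arrays comprised 7 colon tumors, given in the labels as tubular adenomas, and 3 samples of adjacent normal colon epithelium. Mouse 41 and mouse 42 each gave 1 normal sample and 3 tumors, and mouse 43 gave 1 normal sample and 1 tumor. Between 57.7% and 66.7% of the gene probes on an array were above background, and 14478 genes were tested. The number of arrays limits the precision of the values, and the median SE of a tumor minus normal difference was 0.11 on the log2 scale.

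The series was set up to find genes expressed differently in the tumors. Mmp10, a matrix metalloproteinase, was 16.4-fold higher in tumors (log2 difference 4.04 ± 0.31, SE, 7 tumors and 3 normals, limma adjusted p = 3.1e-05). Lcn2, an iron-sequestering protein of inflamed epithelium, was 11.5-fold higher and Hp, which encodes haptoglobin, 11.3-fold higher. The other genes with the largest rises were Mmp13, Ptn, Cfi, Notum, Sp5, Nkd1, Pdgfrl, Wif1 and Prox1, with log2 differences from 3.34 for Mmp13 to 3.19 for Prox1. Cyp2c55, a cytochrome P450, fell by 5.97 ± 0.79 on the log2 scale (adjusted p = 0.00033). The water channel Aqp8 was 39.7-fold lower, the carbonic anhydrase Car4 34.7-fold lower and the chloride-bicarbonate exchanger Slc26a3 25.8-fold lower. 1810065E05Rik, Sult1a1, Slc51a, Gcg, Hao2, Sycn, Pck1 and Mptx1 completed the 12 largest falls, from 32.4-fold for 1810065E05Rik to 17.6-fold for Mptx1. Slc51a was above background in 2 of 7 tumors, and Cyp2c55, Slc26a3, Gcg, Hao2 and Mptx1 in 6 of 7. The rule for naming these 24 genes required all 7 tumors to lie on one side of the normal of the same mouse.

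Over all genes, limma called 3749 higher and 3438 lower in tumors, of which 866 and 785 changed at least 2-fold. With the tumors averaged within each mouse, so that animals are the replicates, the counts were 2738 and 2480. Median scaling gave 4209 and 2675 (61.1% of calls higher, against 52.2%). With the spot median in place of the spot mean the counts were 1354 and 1386, and the authors' deposited table gave 1565 and 1369. They were 2053 and 1937 without mouse 42, where Mptx1 (log2 difference -3.62) no longer passed. Without the normal of mouse 42 and the tumor of mouse 43, the arrays with high squamous genes, and with no block for the mouse they were 3020 and 2844. A later scan session held 4 of the tumors and no normal. The counts were 2692 and 2587 with the session as a block, and 1634 and 1588 within the earlier session, where the fit compared 3 tumors with the normals of 2 mice and 1810065E05Rik (-4.09) no longer passed. Of 117 named genes past the threshold, 67 had a log2 difference that moved by over 1.5 times in at least 1 alternative. With the spot median 40 became smaller, and with no further background correction 21 became larger. In the deposited table, which held 113 of them, 17 became larger and 13 smaller.

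**Figure D1:**
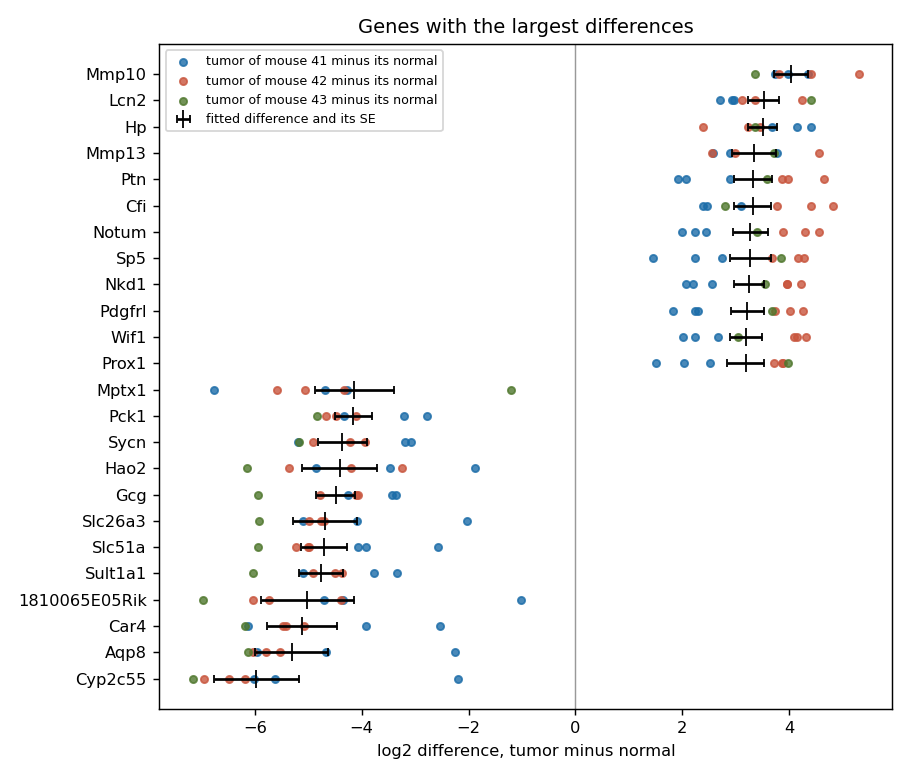
Tumor minus normal differences on the log2 scale for the 12 genes with the largest difference in each direction; points are single tumors minus the normal of the same mouse, and black marks show the fitted difference with its SE. Fitted differences run from -5.97 for Cyp2c55 to 4.04 for Mmp10, and the rule for naming genes required every point to lie on the side of its fitted value.

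Target genes of beta-catenin, the transcriptional effector of Wnt signalling, were mostly higher in tumors, for which the labels give a dominant active Ctnnb1 mutation. Of 22 measured members 19 rose and 1 fell, and adjusted over the list alone also 19 and 1. The intestinal stem cell receptor Lgr5 rose 4.58-fold (log2 difference 2.19 ± 0.16), the Wnt antagonist Dkk2 4.13-fold, Nkd1 9.54-fold and Wif1 9.13-fold. The list passed camera (adjusted p = 6.2e-08; adjusted p = 0.205 with an estimated correlation). Ctnnb1 itself was 1.53-fold higher (log2 difference 0.61 ± 0.14, limma adjusted p = 0.0057, higher in 7 of 7 tumors). Its difference was -0.0032 in the deposited table, and it did not pass with the spot median (0.35). Within the earlier scan session (0.64) and without mouse 42 (0.55) it did not pass at about the same size, with fewer arrays.

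Of 10 measured Paneth cell markers 5 rose and 1 fell, and adjusted over the list alone also 5 and 1. The Paneth score was 1.08 in the normal of mouse 41, against -0.77 and -0.31 in the other normals and 1.02 to 2.47 in the tumors. Mmp7, a matrix protease, rose 7.19-fold, the lectin Itln1 6.37-fold and the lysozyme Lyz1 3.67-fold, whereas Nupr1 was 2.16-fold lower. Nupr1 did not pass within the earlier scan session (log2 difference -1.18) or with the spot median (-0.79). The list had adjusted p = 0.0333, and adjusted p = 0.336 with an estimated correlation. It did not pass with the scan session as a block (adjusted p = 0.0664), within the earlier session (0.115), with the mouse as a random block (0.0666), without both the arrays with high squamous genes and the block for the mouse (0.0902), or without mouse 43 (0.0695). Leaving out only the normal or only the tumor of mouse 43 is the same fit, since the other array then carries no contrast. Among 16 genes of regenerating epithelium 10 rose and 2 fell, and 11 and 2 adjusted over the list alone. The alarmin Il33 rose 4.16-fold, Clu 3.13-fold and Ccn2 2.54-fold (list adjusted p = 0.00732, and adjusted p = 0.194 with an estimated correlation), but Il33 did not pass with the spot median or in the deposited table. Of 28 cell cycle genes 10 rose, also adjusted over the list alone, with the replication licensing factor Mcm4 at 1.70-fold and the sliding clamp Pcna at 1.49-fold; neither passed with the spot median or in the deposited table. This list had adjusted p = 0.0315, adjusted p = 0.606 with an estimated correlation, 0.287 without the normal of mouse 41, 0.0792 without tumor 3 of mouse 41, 0.366 without mouse 41, 0.0891 with the mouse as a random block and 0.0508 in the deposited table.

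Absorptive, goblet and enteroendocrine genes were lower in tumors. Of 21 measured absorptive colonocyte genes 18 fell and none rose, and 21 fell adjusted over the list alone. Slc51a, a bile acid transporter subunit, was 26.1-fold lower (log2 difference -9.01 to -3.52 over the alternatives). The transcription factor Cdx1 was 4.25-fold lower (list adjusted p = 5.3e-08, and adjusted p = 0.214 with an estimated correlation). In tumor 3 of mouse 41 the absorptive score was -1.22, against -2.82 to -2.44 in the other 6 tumors. Of 14 goblet cell genes 13 fell, also adjusted over the list alone, with the secretory lineage factor Atoh1 4.49-fold lower and Klk1 5.74-fold lower, the latter not past the threshold with the spot median. The goblet list had adjusted p = 5.7e-06, and adjusted p = 0.227 with an estimated correlation. All 14 measured enteroendocrine markers fell, also adjusted over the list alone. Chga, a granule protein of hormone-secreting cells, was 6.62-fold lower. Sst, which encodes somatostatin, was 3.56-fold lower and the lineage factor Neurod1 3.07-fold lower, and these were above background in 3 and 1 of 7 tumors. Over the alternatives the log2 differences were -4.03 to -1.20 for Chga, -4.04 to -1.04 for Sst and -4.55 to -1.04 for Neurod1, all past the threshold. This was the only one of the 25 lists past the threshold with an estimated correlation (adjusted p = 0.0414, against 1.3e-09 with the preset one).

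Tuft cell markers went both ways, with 3 of 9 higher and 4 lower, also adjusted over the list alone (list adjusted p = 0.51). Trpm5, a cation channel, was not above background on any tumor array and was at least 3.68-fold lower in this processing (log2 difference -4.17 to -1.15 over the alternatives), while Avil was 4.04-fold higher. Of 27 xenobiotic metabolism genes 17 fell and 1 rose, and 19 and 2 adjusted over the list alone. Cyp3a13 was 8.75-fold lower, the glutathione transferases Gstm3 and Gstt1 3.29-fold and 2.91-fold lower and the glucuronosyltransferase Ugt2b34 3.07-fold lower (list adjusted p = 1.4e-06, and adjusted p = 0.205 with an estimated correlation). The mouse Cyp1a1 probe was not above background on any array. The Cyp1a2 probe was above background on 3 of 10 arrays, at 6.14 to 6.33 over all 10, with a log2 difference of -0.08 ± 0.06 (limma adjusted p = 0.32). With median scaling it passed (-0.22, limma adjusted p = 0.046). These mice carry human CYP1A genes in place of the mouse ones, so its signal was not read as mouse Cyp1a2. Of 19 genes of fatty acid oxidation and ketogenesis 17 fell, also adjusted over the list alone, with Echs1 2.33-fold lower, Acaa2 2.26-fold lower and Acadm 1.86-fold lower (list adjusted p = 2.2e-07, and adjusted p = 0.205 with an estimated correlation). In tumor 3 of mouse 41 the scores of these lists were -0.99 for xenobiotic metabolism and -0.59 for fatty acid oxidation. Glycolysis genes did not pass as a list (adjusted p = 0.173), with 2 of 16 higher and 6 lower, also adjusted over the list alone. Hk1 was 2.13-fold lower (log2 difference -1.09). It did not pass with the spot median (-0.64), in the deposited table (-0.75) or, at about the same size, within the earlier scan session (-1.03). Pkm was 1.36-fold higher (0.45) and did not pass within the earlier scan session at the same size (0.45), with fewer arrays.

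Fibroblast, matrix protease, inflammatory, myeloid and endothelial genes were mostly higher in tumors. Of 20 fibroblast and matrix genes 18 rose and 1 fell, also adjusted over the list alone. Fibronectin (Fn1) rose 5.16-fold (log2 difference 2.37 ± 0.08), decorin (Dcn) 3.67-fold and the receptor Pdgfra 3.31-fold (list adjusted p = 6.2e-08, and adjusted p = 0.227 with an estimated correlation). All 13 measured matrix proteases and inhibitors rose, also adjusted over the list alone, with Timp1 at 5.07-fold, Mmp2 at 4.17-fold and Mmp14 at 3.26-fold (adjusted p = 6.3e-08, and adjusted p = 0.0618 with an estimated correlation). Of 20 inflammatory mediators 16 rose, and 17 adjusted over the list alone, with Saa3 at 7.18-fold, the neutrophil chemokine Cxcl1 at 5.22-fold and Il1b at 4.36-fold (adjusted p = 5.7e-06, and adjusted p = 0.205 with an estimated correlation). Macrophage markers rose in 8 of 10 cases, also adjusted over the list alone, with the complement genes C1qa at 4.26-fold and C1qc at 3.94-fold (adjusted p = 7.2e-05, and adjusted p = 0.21 with an estimated correlation). Neutrophil markers rose in 9 of 11 cases, also adjusted over the list alone, with S100a8 at 5.64-fold and Csf3r at 2.59-fold (adjusted p = 0.00077, and adjusted p = 0.336 with an estimated correlation). The neutrophil score was 0.68 in the normal of mouse 42 and 1.58 in the tumor of mouse 43, the arrays that also had the highest squamous scores. Endothelial markers rose in 11 of 12 cases, and 12 adjusted over the list alone, with Vwf at 2.13-fold and Eng at 2.03-fold (adjusted p = 3.7e-05, and adjusted p = 0.208 with an estimated correlation). With the spot median Timp1, Mmp14, Vwf and Eng did not pass, nor did Mmp14 and Vwf in the deposited table.

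Of 9 B and plasma cell markers 5 fell, also adjusted over the list alone, with the B cell receptor component Cd79b 2.48-fold lower (adjusted p = 0.0142, adjusted p = 0.336 with an estimated correlation, 0.0563 without mouse 41, and 0.0593 without the arrays with high squamous genes and the block for the mouse). T cell markers did not pass as a list (adjusted p = 0.154), with 3 of 14 higher and 1 lower, also adjusted over the list alone. The kinase Zap70 was 3.69-fold higher. Of 10 smooth muscle markers 5 fell, also adjusted over the list alone, with Des 1.97-fold lower (adjusted p = 0.028, and adjusted p = 0.336 with an estimated correlation). The smooth muscle list did not pass without the mouse as a block (adjusted p = 0.131, and 0.162 also without the arrays with high squamous genes), with the scan session as a further block (0.0664), with the spot median (0.167), in the deposited table (0.341), without the normal of mouse 41 (0.15), without mouse 41 (0.136), with the mouse as a random block (0.195) or with genes above background on all 10 arrays (0.0598). Des did not pass without the normal of mouse 41 or without mouse 41 (log2 difference -0.68 each), within the earlier session (-0.75) or with the session as a block (-0.64). Nor did it with the spot median (-0.81) or in the deposited table (-1.05), against -0.98 in the main fit. Myh11 fell by 0.70 on the log2 scale, but stood at 0.011 in the deposited table and at -0.044 with the spot median, neither past the threshold. At -0.56 to -0.54 it also did not pass without the mouse as a block, with it as a random block, without the normal of mouse 41, within the earlier session or with the session as a block.

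NRF2 targets (7 of 14 higher, 3 lower) and p53 targets (7 of 16 higher, 2 lower) each had adjusted p = 0.14, with the same counts adjusted over the list alone. Hmox1, the heme oxygenase, was 4.61-fold higher and Phlda3 3.39-fold higher. The NRF2 list passed without the normal of mouse 42 (adjusted p = 0.0365) and without mouse 42 (0.0407), and the p53 list with all kept probes tested (0.0313). Of 4 adipocyte markers 3 fell, also adjusted over the list alone (list adjusted p = 0.0531), and Cfd was at least 1.51-fold lower in this processing (log2 difference -4.08 to -0.53 over the alternatives). The list passed without the normal of mouse 42 (0.0148), tumor 2 of mouse 42 (0.0333) or mouse 42 (0.0129), with the spot median (0.0169), median scaling (0.0256), all kept probes (0.0345), an offset of 16 (0.0356) or no further background correction (0.0408). Of 3 enteric neuron and glia markers 1 rose, and 1 rose and 1 fell adjusted over the list alone (list adjusted p = 0.744; median -0.15, mean 0.07). Of 10 squamous epithelium markers 2 fell, also adjusted over the list alone (list adjusted p = 0.309). The list passed without mouse 43 (0.0124, the same fit as without only its normal or only its tumor), within the earlier scan session (0.0217) and in the deposited table (0.0276). The squamous score was 1.53 in the normal of mouse 42 and 1.43 in the tumor of mouse 43, against -1.22 to -0.59 on the other 8 arrays. In all, 17 of 25 lists passed camera with the preset correlation, 1 with an estimated correlation, 15 with the scan session as a block and 17 within the earlier session. Fry, which does not compare a list with other genes, passed 20, of which 16 also passed camera. Cell cycle genes did not pass it (adjusted p = 0.0702), whereas the tuft cell (0.00157), NRF2 (0.00163), p53 (0.00725) and adipocyte (0.00474) lists did. Other splits of the arrays into 7 and 3 passed as many as 20 lists, and at most 14 where the set of 3 held 1 normal.

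**Figure D2:**
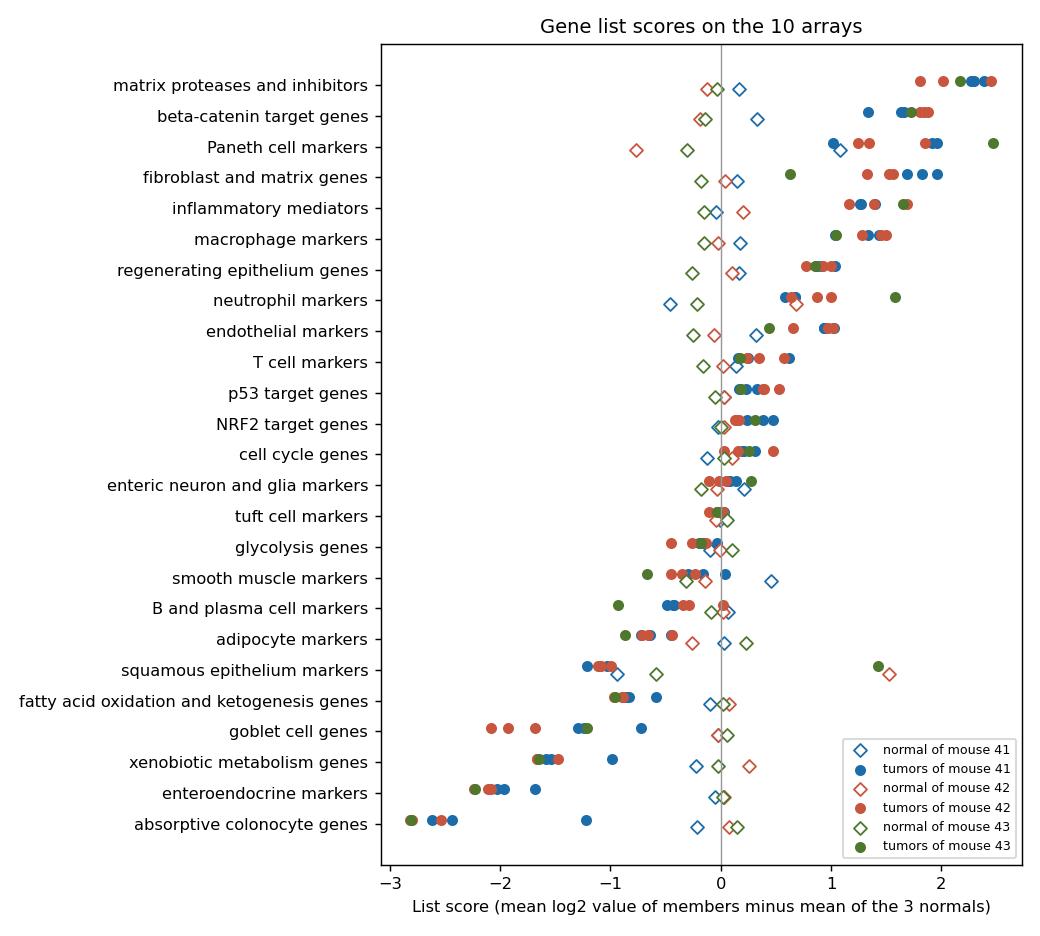
Scores of the 25 gene lists on each array, as the mean log2 value of the members minus the mean of the 3 normals; diamonds are normals, circles are tumors and colours mark the mouse. Absorptive scores of the tumors run from -2.82 to -1.22, and the normal of mouse 42 and the tumor of mouse 43 stand apart in the squamous list at 1.53 and 1.43.

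**Figure D3:**
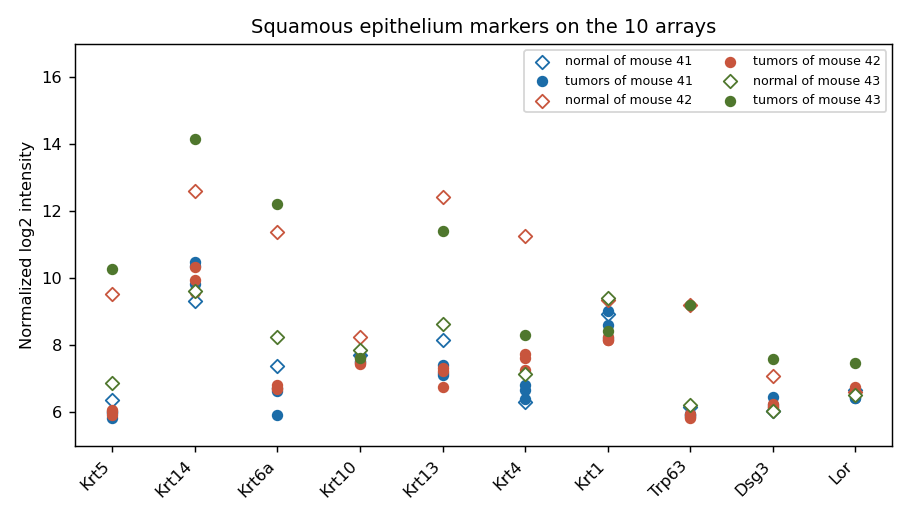
Normalized log2 intensity of the 10 measured squamous epithelium markers on each of the 10 arrays; diamonds are normals, circles are tumors and colours mark the mouse. For 7 of the 10 genes the highest pair of arrays is the normal of mouse 42 and the tumor of mouse 43.

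The labels give mouse 42 as female and mouse 41 and mouse 43 as male, so mouse and sex cannot be told apart in comparisons between these animals. The probes for the Y-linked genes Ddx3y, Eif2s3y and Kdm5d were above background on all 10 arrays. In the normals of mouse 41 and of mouse 42, labelled female, the log2 levels were 9.23 and 9.25 for Ddx3y, 10.23 and 10.31 for Eif2s3y and 7.73 and 7.75 for Kdm5d. For Uty 1 probe was above background on 3 of 10 arrays, at 6.45 and 6.63 in these normals, and the other on none. No probe for Xist was measured. Whether these probes also bind X-linked relatives, or the sex label of mouse 42 is wrong, was not tested.

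The tumors of mouse 42, labelled female, differed from those of mouse 41 in 32 genes (3 tumors each), with 18 higher in mouse 42 and 14 higher in mouse 41. The normals of the mice, 1 each, also differed: the median ratio of the normal to the tumor difference was 0.46 over 8 genes that lie in one stretch of a chromosome and 0.82 over the other 24. The hemoglobin genes Hba-a1 and Hbb-b2 were higher in mouse 42 by 2.07 ± 0.19 and 1.84 ± 0.22 on the log2 scale, and the GABA transporter Slc6a13 by 2.04 ± 0.21 (limma adjusted p = 0.019). The transcripts XM_144817 and XM_355779 were higher by 4.03 and 1.91. Mgst1, a microsomal glutathione transferase, was lower in mouse 42 with a log2 difference of -2.43 ± 0.24, followed by Styk1 (-1.48), the clock-controlled gene Dbp (-1.28), Chil3 (-1.27) and B3gnt3 (-1.17). The count was 9 with the scan session as a block, 1 with the spot median, 15 in the deposited table and 146 with median scaling, and within the earlier session limma called 0 genes, with 707 at an unadjusted p under 0.05. That session held 2 tumors of mouse 41 and 1 of mouse 42, with 1 residual degree of freedom, so its count does not show whether the calls depend on the session. The count was 111, 5 and 15 without tumor 1, 2 and 3 of mouse 41, and 2 and 4 without tumor 2 and 3 of mouse 42. None of the 10 genes passed without either of the latter. Their differences stayed about as large there, at -2.48 and -2.56 for Mgst1 and 1.97 and 1.94 for Hba-a1, with fewer arrays. Of the 10, 9 did not pass with the spot median or without tumor 2 of mouse 41, 7 with the session as a block, 6 in the deposited table, 5 with no filter on dim probes, 4 without tumor 3 of mouse 41 or tumor 1 of mouse 42, and 3 with no further background correction. With the session as a block and without tumor 2 of mouse 41 the sizes held, at -2.35 and -2.46 for Mgst1. With the spot median those 9 were smaller, at -0.59 for Dbp and 0.87 for XM_355779 but -1.10 for B3gnt3.

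For the tumor minus normal difference, limma called 58 genes between mouse 42 and mouse 41, with 49 more negative in mouse 42. Each normal is 1 array in this fit, assumed to vary as the tumors do, and its spread was not measured. With both normals in place, the 18 splits that mix the tumors of the mice called 28 to 39 genes, and exchanging the tumors called 98, among them 53 of the 58. At least 1 mixed split called 51 of the 58, so the calls are not shown to be differences between the tumors. The largest negative values were those of Psca (-4.59 ± 0.48), the platelet chemokine Ppbp (-4.39), Slurp1 (-4.14) and the keratins Krt13 (-4.41) and Krt4 (-4.05), which belong to the squamous list. The normal of mouse 42 was the highest array for Psca, Slurp1, Krt13 and Krt4, at 13.54 for Psca, and the next highest for Ppbp, at 12.72. In the other direction stood Dusp22 (6.64 ± 0.18), Isyna1 (4.07), NM_009669 (3.01), Ush1g (2.35) and Lyz1 (1.75). These sizes depended on the processing. With the spot median the differences were 0.86 for Dusp22, 1.63 for Isyna1, 2.09 for NM_009669 and 0.50 for Ush1g. In the deposited table they were 2.10 for Dusp22 and 1.65 for Isyna1, while with no further background correction that of Ush1g was larger, at 4.88. Dusp22 was at 13.27 in the normal of mouse 41 and between 6.26 and 6.73 on the other 9 arrays. The count was 41 with the scan session as a block, 9 with the spot median and 0 within the earlier session (limma, 494 genes at an unadjusted p under 0.05), where the 2 tumors of mouse 41, 1 tumor of mouse 42 and 1 normal of each mouse again leave 1 residual degree of freedom and decide nothing. The count was 30 without tumor 2 of mouse 42, where Psca (-4.52) and Ppbp (-4.27) did not pass at about the same size, and 35 without tumor 3 of mouse 42. Lyz1 changed sign with the spot median (-0.21). At about the same size it did not pass without tumor 2 of mouse 41 (1.71) or without tumor 1, 2 or 3 of mouse 42 (1.75, 1.67 and 1.83). Besides Lyz1, 6 of these 10 genes did not pass with the spot median and 4 in the deposited table, and 5 with Lyz1 among them did not with no further background correction.

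Tumors of the same mouse resembled each other more than tumors of different mice did over all pairs. The mean distance, 1 minus Pearson's r across genes, was 0.0125 ± 0.0043 (SD, 6 pairs) within a mouse and 0.0230 ± 0.0088 (SD, 15 pairs) between mice. The difference of 0.0105 gave p = 0.014 in an exact one-sided permutation of the mouse labels, the smallest p that the 140 assignments allow. Over pairs scanned in 1 session the difference was 0.0073 (exact permutation p = 0.17, with 0.056 the smallest possible), within the earlier session 0.0025 (exact permutation p = 0.67, with 0.33 the smallest that its 3 tumors allow), and without the tumor of mouse 43 0.0074 (exact permutation p = 0.1). The first principal component held 69.3% of the variance and separated tumors from normals, with tumor 3 of mouse 41 at 1.79 and the other tumors between 23.0 and 38.7.

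**Figure D4:**
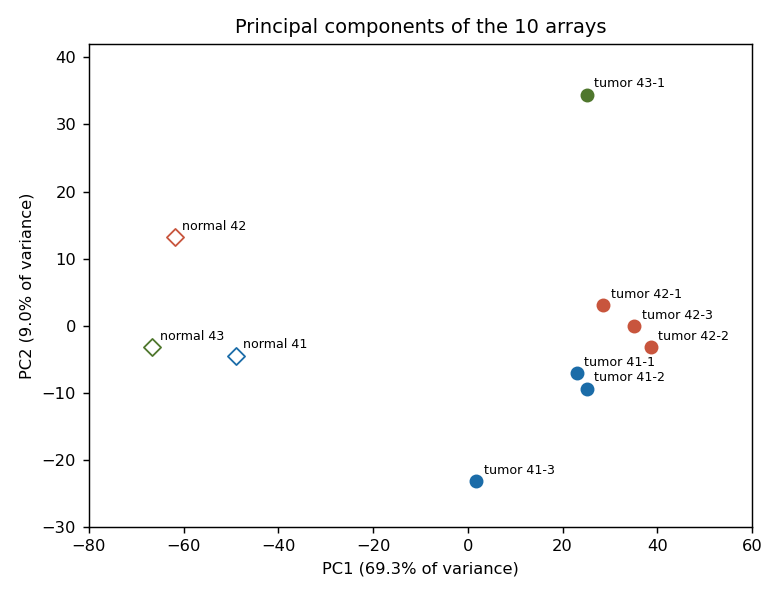
Scores of the 10 arrays on the first principal component (69.3% of the variance) and the next (9.0%); diamonds are normals, circles are tumors and colours mark the mouse. The normals lie at -66.6 to -49.0 on the first component and the tumors at 1.79 to 38.7.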

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

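The tests of a squamous tissue source, of normal epithelium or the scan session in tumor 3 of mouse 41, of chance placement, of a difference shared by normal and tumor and of splits by their number of normals or shared calls were chosen only after the result was seen. Of 171 values checked, 27 had a tumor far from the other 6, with 12 in the tumor of mouse 43 and 10 in tumor 3 of mouse 41. For a single value chance gives a flag about 1 time in 20. The values are not independent, since list scores were checked beside members of the same lists. The count of 27 therefore does not measure an excess over chance.

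The tumor of mouse 43 stood apart with a squamous list score of 1.43 and Krt13 of that list at 11.41, and with Psca at 13.03, Ppbp at 14.02 and Slurp1 at 6.96, which are not on the list; the tumor minus normal difference of mouse 42 minus that of mouse 41, with 1 normal each, was -4.59 for Psca, -4.41 for Krt13, -4.39 for Ppbp, -4.14 for Slurp1 and -4.05 for Krt4. Transfer of RNA between these 2 samples was looked at in both directions. In the normal of mouse 42 the 12 genes highest in tumors had a median difference of -0.64 from the other normals. In the tumor of mouse 43 the 12 genes lowest in tumors had a median of -1.21 from the other tumors. Both sets were picked for large differences with these arrays among those compared, which biases the medians downward, so they do not decide. On the first principal component, over all genes, the normal of mouse 42 (-61.8) lay among the normals and the tumor of mouse 43 (25.1) among the tumors. On the next component (9.0% of the variance) they were the 2 highest arrays, at 13.2 and 34.5, with the others at most at 3.03. Neither whole profile lay toward the other tissue on the first component. A sample that only received RNA should not stand above its source. Krt4 (11.26 against 8.30) and Krt13 (12.44 against 11.41) were higher in the normal of mouse 42. Krt14, Krt6a (11.40 against 12.23), Krt5 (9.52 against 10.28) and Dsg3 (7.09 against 7.58) were higher in the tumor of mouse 43. Trp63 was alike (9.20 and 9.21). With 1 array each, these values argue against transfer in 1 direction as the whole cause, and a smaller transfer stays open. The normal of mouse 42 and the tumor of mouse 43 were the highest pair of arrays for 7 of 10 measured list members, with Krt14 at 12.60 and 14.17. This count restates the pattern, so squamous tissue in both samples stays open, and the design gives no group for a biological explanation.

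Tumor 3 of mouse 41 kept more colonocyte expression, with scores of -1.22 for absorptive, -0.99 for xenobiotic and -0.59 for fatty acid oxidation genes, 1.79 on the first principal component, and log2 levels of 13.56 for 1810065E05Rik, 10.54 for Aqp8, 10.42 for Cyp2c55, 9.56 for Slc26a3 and 7.48 for Slc51a. Normal epithelium like that of the same mouse in the sample would give every epithelial gene one share of normal RNA. Only list members called lower in tumors were used. The median share was 30.0% for 18 absorptive genes, 53.5% for goblet genes and -4.27% for 14 enteroendocrine genes. Single genes ran from -65.1% to 108%, from -47.6% to 94.8% and from -18.8% to 21.6%. For the absorptive genes that fell most, Cyp2c55, Aqp8, Car4, Slc51a and Slc26a3, it was 11.3% to 20.9%. Enteroendocrine minus absorptive was -34.3 percentage points (two-sided permutation test over genes, which are not independent replicates, p = 0.0008). This difference argues against such normal epithelium as the whole cause. The scan session is argued against, since the score lay 1.22 above the highest other tumor of that session. Epithelium with few enteroendocrine cells, and a more differentiated tumor, stay open as hypotheses; the design gives no group for either.

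Of the 29 genes with a placed symbol that differed between the tumors of mouse 42 and mouse 41, 8 lie in one stretch of 1 chromosome in the GRCm38.p6 table: Slc6a13, Styk1, Lrp6, Dusp16, H2aj, Eps8, Mgst1 and Iapp, 5 of which were named after their values were seen. Chance placement is argued against (Fisher's exact test, two-sided, p = 0.0019 after multiplying by 21 chromosomes). One copy number shift of the whole stretch in the tumors is argued against by a median difference of -0.066 over its 135 tested genes, with 2 of the 8 higher and 6 lower in mouse 42. The scan session as the whole cause is argued against, since with it in the fit the differences were 0.97 to 1.07 times as large (median 1.01), but 4 of the 8 no longer passed (limma adjusted p 0.0598 to 0.0895), with a median SE of 0.124 in place of 0.116 and 3 residual degrees of freedom in place of 4. A difference between the animals shared by normal and tumor cannot be told apart for these genes as a set. The normals, 1 per mouse, differed in the same direction for 7 of 8, at a median ratio of 0.46 to the tumor difference. That ratio was 0.82 over the other 24 genes called between these tumors. It varied by gene. The normals and the tumors differed by 1.52 and 1.61 for Lrp6, -1.14 and -1.11 for Dusp16 and -0.83 and -1.04 for H2aj. For Mgst1 these were -1.65 and -2.43. The normals differed less for Slc6a13 (0.45 and 2.04), Styk1 (-0.35 and -1.48), Eps8 (-0.017 and -0.96) and Iapp (0.12 and -0.86). The labelled sex stays open, untested.

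Among the single values far from the other tumors, the neutrophil score of the tumor of mouse 43 was 1.58, and its levels were 8.64 for Fpr2, 11.04 for Col4a1, 10.97 for Pdgfra, 6.08 for Fabp4, 7.56 for Gstt1 and 7.04 for Kdm5d. Trpm5 was at 6.33 in tumor 3 of mouse 41 and not above background on any tumor array. Car3 was at 7.41 in tumor 2 of mouse 42 and Mmp7 at 13.01 in tumor 1 of mouse 42. Tumor 1 of mouse 41 had 55 saturated spots, a median gene probe signal of 72 and a ratio of spot median to spot mean on bright spots of 0.82, against 0.40 to 0.57 in the other tumors. The difference of effects, mouse 42 minus mouse 41 with 1 normal each, was also past the threshold for Dusp22 (6.64), Isyna1 (4.07), NM_009669 (3.01), Ush1g (2.35) and Lyz1 (1.75). With the spot median these were 0.86, 1.63, 2.09, 0.50 and -0.21. Outside the gene probes, 4 of 75 virus-named probes above background were higher in tumors and 5 lower, as were 26 and 11 of 426 probes of another mouse class and 2 and 3 of 7 negative control probes. These 7 were the ones of 94 negative control probes that passed the filter, and what they bound was not tested. Of the tested genes 49.6% were called. The other classes were scaled by each array's median over the gene probes, not quantile normalized. Their p-values were adjusted within each class, so the shares are not directly comparable.

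Other splits of the arrays bear on the counts. The real split was the largest of 100 drawn from the splits of the 10 arrays into 7 and 3 (1 as large). It called 3749 genes higher against at most 3, and 3438 lower against at most 7. Every other split leaves part of the contrast of tumor and normal in its residual, so low counts there were largely fixed in advance. The splits also treat the tumors of 1 animal as exchangeable, so chance at the level of the 3 animals is not excluded. Of the 27 drawn that set apart 1 array of each mouse, 1 was as large and the highest other called 0 in limma, with 62 to 3455 genes at an unadjusted p under 0.05. For the lists 16 of the 100 splits passed at least the 17 lists, and the highest passed 20, so these splits do not exclude chance. The others as large point to a structure of the samples: 6 had 2 normals in the set of 3 and 9 had none, and so kept part of the contrast of tumor and normal, while the 52 splits with 1 normal there passed 1 to 14 lists. The 10 splits of the tumors of mouse 42 and 41 are too few for a share under 0.05; the real value was 32 (1 as large) and the highest other 0 in limma, with 209 to 1313 genes at an unadjusted p under 0.05. The 20 splits for the difference of effects are also too few, with 58 genes against 98 in the highest other (2 as large), which exchanges the tumors of the mice, and the rest called 28 to 39. Every split kept the normal of each mouse in place, and 53 of the 58 genes were also called with the tumors exchanged, which points to the single normals.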

How the results depend on the processing

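The spot median, the scan session and the 2 squamous arrays, with and without the block, were chosen as alternatives after seeing the data. Leaving out each array in turn gave 2575 to 3882 genes higher and 2412 to 3478 lower in tumors, 2 to 111 between the tumors of mouse 42 and 41, 30 to 61 for the difference of effects, a distance difference of 0.0074 to 0.0140 and 15 to 19 lists. Genes higher and lower numbered 1565 and 1369 from the deposited table, 866 and 785 with a log2 difference of at least 1, 1634 and 1588 without the 4 redipped or rescanned arrays, 2053 and 1937 without mouse 42, 1354 and 1386 from the spot median and 1234 and 1276 without the squamous arrays, where only mouse 41 keeps both tissues, so that 1 normal decides and the squamous arrays are not tested; with no replicate block either they were 3020 and 2844, with 14 lists. Of the 2740 spot median calls, 2674 were also called from the spot mean, 2673 in the same direction. With no replicate block the counts were 3670 and 3422, and with tumors averaged within each mouse and the replicate block 2738 and 2480; without the block 16 lists passed, and smooth muscle was the only list call lost. Between the tumors of mouse 42 and 41 the counts were 146 with median scaling, 15 from the deposited table, 21 with no filter, 53 with trend and robust eBayes, 20 with a log2 difference of at least 1, 0 without the redipped or rescanned arrays (limma, 707 at an unadjusted p under 0.05), 1 from the spot median and 9 with the scan session. For the difference of effects they were 20 with no further background correction, 23 above background on all 10 arrays, 0 without the redipped or rescanned arrays (494 unadjusted) and 9 from the spot median. Without those 4 arrays 2 tumors of mouse 41 and 1 of mouse 42 were left, so neither 0 shows a loss of calls. The distance difference could not pass without those arrays (0.0025, smallest possible p 0.33), without the squamous arrays (0.0074, exact permutation p = 0.1, the smallest that 6 tumors of 2 mice allow) or over pairs of 1 session (0.0073, smallest possible p 0.056). With an estimated correlation 1 list passed. Fewer arrays or a stricter threshold are part of some settings; otherwise the cause was not tested. Signs turned in the deposited table for Ctnnb1 (-0.0032), Gpx2 (-0.044), Myh11 (0.011) and the effect difference of Lyz1 (-0.21, also -0.21 from the spot median), and for Krt4 without the normal of mouse 42 (0.65), where leaving out single arrays gave -1.77 to 0.65. Signs also turned, with neither value past the threshold, for Krt13 without the normal of mouse 42 or mouse 42 (0.55), Krt4 without mouse 42 (0.65) or the squamous arrays (0.33, and 0.36 with no block) and Fabp4 without the redipped or rescanned (0.025) or squamous arrays (0.027, and 0.063 with no block). Of the values of named genes between tumor and normal, 3609 stayed on their side of the threshold, 191 lost and 13 gained a call. Sign turns with neither value past the threshold are counted among those that stayed. Of the list results 691 stayed, 40 lost and 17 gained a call. Between the mice 161 values of named genes stayed and 77 lost a call, and for the difference of effects 169 stayed and 33 lost one. The share of probes above background, at most 66.7% of an array, limits dim genes.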

Other observations

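The genes given here were chosen after their values were seen. Hba-a1 was at 13.60 in the normal of mouse 42 and at 10.36 and 10.99 in the normals of mouse 41 and mouse 43, and Hbb-b2 at 10.53, 8.13 and 8.37. Dbp was at 8.08 in the normal of mouse 42 and at 10.43 and 10.77 in the other normals. Single arrays also held isolated high values: NM_009669 was at 15.16 in the normal of mouse 43, and Isyna1 at 13.89 in the normal of mouse 41.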
